A study of Mus musculus with 17 samples.

How the data were processed

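RNA was measured in 17 mouse libraries that fall into 4 experiments, each with its own table of gene counts. Primary neurons of the C57BL/6 strain gave 14 of the libraries and hippocampi of mice given a short hairpin RNA (shRNA) gave 3. Per the labels, total RNA was taken up in Trizol, 2 μg per sample went into the NEBNext Ultra RNA kit, and the libraries were sequenced on an Illumina instrument. The submitters' processing notes name Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the mouse genome build mm10. The role of each tool, the strand setting and any selection of poly(A) RNA are not given in the sources used here. The deposited values are raw counts per gene, whole numbers with a different total in each library, and no normalization had been applied. Library totals ran from 14.62 M to 19.14 M counts.

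The neuron libraries form 7 groups of 2 libraries each. They are an ADM group with its control, a first set with control and ApoE particle neurons (set 1), and a second set with control, ApoE particle and reconstituted ApoE particle neurons (set 2). The labels do not spell out ADM, and they do not say whether 2 libraries of a group came from separate cultures. Every p-value here therefore measures the spread between these samples only. The hippocampus groups hold 1 library each: control shRNA without FC, control shRNA with FC, and ApoE shRNA with FC, where FC is not spelled out in the labels.

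The tables listed 31762 genes (ADM), 30552 (set 1), 30984 (set 2) and 24652 (hippocampus), and 31651, 30483, 30908 and 24597 of their identifiers were found in the reference gene names. Gene symbols stored as dates, 25 in each neuron table and 24 in the hippocampus table, were restored from the gene identifier. In set 2, 1489 genes held values for the reconstituted particle libraries but none for the control and ApoE particle libraries, so they were left out of the tests. No set 1 library had the same counts as a set 2 library over the genes in both tables (0 pairs), and all per-sample columns were used.

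Each neuron comparison was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and dispersions were estimated robustly. The quasi-likelihood F test then gave p-values, which were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold. The 3 groups of set 2 shared a single fit. There were 7 comparisons: ADM against its control, the ApoE particle against control in set 1 and in set 2, the reconstituted particle against control and against the ApoE particle in set 2, the difference of the ApoE particle effect between set 2 and set 1, and the difference between the ADM effect and the set 1 particle effect. The last 2 were interaction terms on the genes listed in both tables. Fold changes are log2 values given with ± 1 standard error, and expression levels are in CPM (counts scaled to a common library total) and given with ± 1 SD over 2 libraries, unless stated otherwise.

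The groups of genes were 27 lists fixed before the data were examined. They cover cholesterol synthesis, sterol sensing and uptake, LXR targets and cholesterol efflux, fatty acid and acetyl-CoA metabolism, ApoE receptors, activity-induced genes, histone acetyltransferases and deacetylases, synapse, integrated stress response, endoplasmic reticulum stress, inflammation, interferon response, glycolysis and hypoxia, lysosome and autophagy, heat shock and oxidative stress, and axon growth and cytoskeleton. Marker lists cover astrocytes, microglia, the oligodendrocyte lineage, vessels and fibroblasts, erythrocytes, choroid plexus, proliferating cells, excitatory neurons, inhibitory neurons, hippocampal regions and mitochondrially encoded transcripts. Each list with at least 3 measured members was tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, against all other genes, and adjusted over the lists of a comparison. Each list is also read in 2 other ways: the number of members called when p-values were adjusted over the list alone, and the camera test with an inter-gene correlation estimated from the data.

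The genes named in the text were chosen by a rule set before the data were examined. For each comparison it takes the 6 largest rises and 6 largest falls among called genes with non-overlapping libraries and at least 5 CPM in the higher group, leaving out unnamed predicted genes. From each list it takes up to 4 called members with the lowest adjusted p, or up to 2 members with the lowest unadjusted p where none was called. Apoe is given in every comparison.

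The hippocampus groups have no replicates and were not tested; log2 ratios of CPM with a prior of 0.5 counts are given for genes with at least 100 counts in the higher library. Each ratio carries an exact 95% interval from the binomial distribution of the 2 counts. A list's median ratio was placed among 10000 random lists matched on mean expression in 20 bins. Where all libraries of a group had 0 counts, the fold was computed against 3 counts over the group, the largest number that a count of 0 allows. These intervals and floors cover counting error only. Genes named for a hippocampus comparison are the 6 largest rises, the 6 largest falls and up to 4 members of each list with the largest ratios.

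The tests were checked on simulated data that kept each table's library sizes and gene-wise dispersions. With a planted change of 1 log2 unit, 80.0% of the genes were recovered in set 1, 80.6% with the ApoE particle in set 2 and 80.3% with the reconstituted particle, but 7.81% for ADM. With 2 log2 units, 68.9% were recovered for ADM. Of the calls on simulated data, 38 of 190 in set 1, 22 of 188 in set 2 and 22 of 69 for ADM were genes without a planted change, so calls near the threshold are less certain than the adjusted p states. A planted list of 20 genes lowered by 0.5 was called by camera in set 1 (adjusted p = 1.11e-20) and set 2 (adjusted p = 1.52e-24), not for ADM (adjusted p = 0.106). With an estimated correlation its adjusted p was 0.998 for ADM, 0.979 in set 1 and 0.0375 in set 2. For ADM and set 1 a missing call with an estimated correlation therefore does not decide whether a list changed. None of 25 unchanged lists (0) was called in any comparison. The genes were simulated independently of each other, so this check cannot show how often camera calls an unchanged list of correlated genes.

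The alternatives tried were edgeR's median-of-ratios scaling, scaling by library totals only, the Wald test of DESeq2 1.42.0, no filter on low counts, a stricter filter of 5 CPM, a minimum absolute log2 fold change of 1, a replicate block, leaving out each library in turn, a fit restricted to the groups compared, and, for lists, the estimated correlation and the rotation test fry. For the hippocampus they were TMM scaling, a prior of 5 and a minimum of 10 counts. A crossed replicate block for set 2 was added after the data had been seen.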

Results

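The data are RNA-seq counts from 14 libraries of mouse primary neurons and 3 libraries of mouse hippocampus. Each neuron group held 2 libraries, with totals of 16.8 and 19.14 M counts (ADM control), 14.62 and 16.73 M (ADM), 15.82 and 17.7 M (set 1 control), 15.79 and 17.12 M (set 1 ApoE particle), 17.56 and 17.26 M (set 2 control), 16.97 and 17.78 M (set 2 ApoE particle), and 16.49 and 16.85 M (set 2 reconstituted particle). The hippocampus libraries held 18.17 M (control shRNA without FC), 17.79 M (control shRNA with FC) and 18.9 M counts (ApoE shRNA with FC). In every neuron group the 2 libraries differed by more than sampling noise, with a chi-square per degree of freedom from 2.63 (set 1 ApoE particle) to 68.1 (ADM). Apoe itself was measured at 1382 ± 322 CPM (SD, n = 2) in the set 1 controls, 672 ± 18.8 in the set 2 controls and 396 ± 332 in the ADM controls.

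The ApoE particle comparison asks which transcripts of primary neurons respond to a particle that carries ApoE, the main apolipoprotein of the brain. In set 1 the genes of cholesterol synthesis fell together: 19 of the 20 measured enzymes fell, and 20 when adjusted over the list alone, with a median log2 fold change of −1.63 (camera, adjusted p = 1.05e-18, and 0.359 with an estimated correlation). Mvd (ENSMUSG00000006517, minus strand of chromosome 8, 122433601 to 122443422 in mm10), which makes isopentenyl diphosphate from mevalonate diphosphate, fell from 105 ± 4.86 to 15.9 ± 2.13 CPM (log2 fold change −2.73 ± 0.11, adjusted p = 8.83e-07). Hmgcs1, the synthase ahead of the rate-limiting step, fell from 1263 ± 24.6 to 345 ± 24.7 CPM (−1.87 ± 0.10), and Dhcr7 and Msmo1, which act late in the pathway, fell by 1.76 and 1.73. Ebp, named after its values were seen, was the enzyme that missed the threshold over all genes (−0.43 ± 0.19, adjusted p = 0.0994).

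Genes outside the pathway that sterols are known to repress fell in the same libraries. Stard4, a sterol carrier, Insig1, the sterol sensor that retains SREBP, and Srebf2, which encodes SREBP2, had log2 fold changes of −1.78 ± 0.12, −1.50 ± 0.10 and −0.94 ± 0.09. The sterol sensing and uptake list had 5 falls and 3 rises among 10 genes, 6 and 3 when adjusted over the list alone (median −0.48, adjusted p = 0.0147, and 0.359 with an estimated correlation). Fatty acid and acetyl-CoA genes had 11 falls and 1 rise among 16, 12 and 2 over the list alone (median −0.47, adjusted p = 8.34e-05, and 0.359 with an estimated correlation). Among them were Acly, which supplies cytosolic acetyl-CoA (−1.14 ± 0.10), Elovl6 (−1.13 ± 0.09) and the fatty acid synthase Fasn (−1.04 ± 0.10). Abca1, the cholesterol exporter that LXR induces, rose from 314 ± 17.1 to 676 ± 32.5 CPM (1.11 ± 0.09, adjusted p = 8.99e-06), and Soat1, which esterifies cholesterol, rose by 0.84, while Cyp46a1, which hydroxylates cholesterol in neurons, fell by 0.63. The LXR list as a whole had 5 rises and 3 falls among 13 genes (adjusted p = 0.437), the same numbers when adjusted over the list alone. ApoE receptor genes had 6 rises and 2 falls among 13, the same numbers over the list alone (median 0.29, adjusted p = 0.0211, and 0.402 with an estimated correlation), led by Lrp2 or megalin (2.29 ± 0.12, from 25.5 ± 3.15 to 125 ± 17.7 CPM). That list call ended without the first control library (adjusted p = 0.109).

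**Figure D1:**
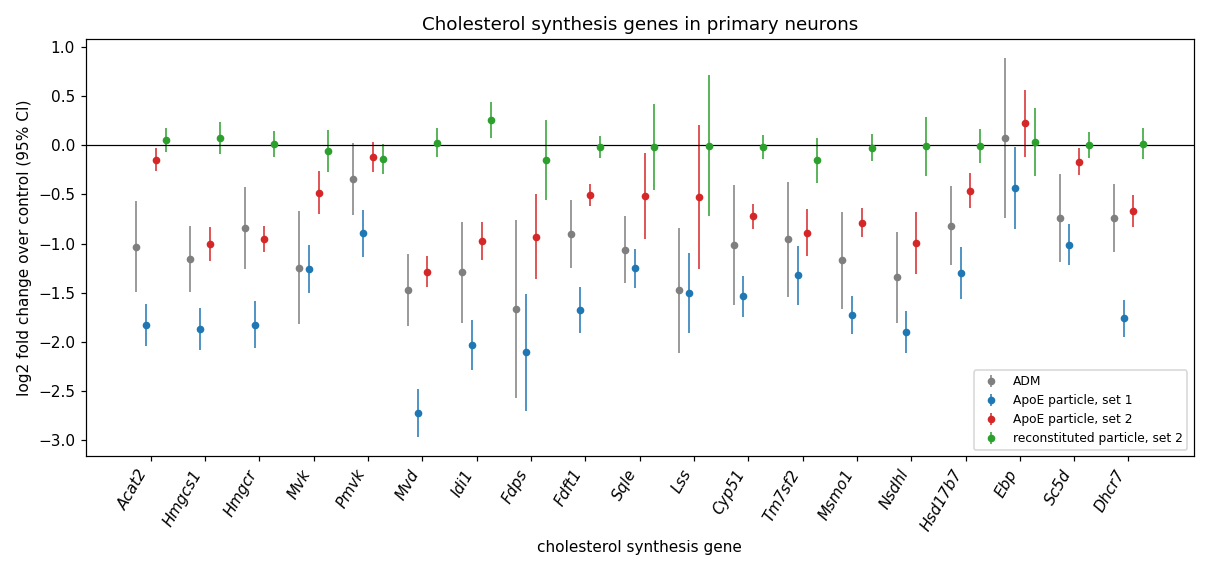
Log2 fold change over control (vertical axis) of 19 cholesterol synthesis genes (horizontal axis) in the 4 neuron comparisons, 2 libraries per group, with points for the edgeR estimate and bars for its 95% confidence interval. The set 1 points reach −2.73 at Mvd and the set 2 points −1.29, and the whole list has a median of −0.01 with the reconstituted particle.

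Neuronal transcripts fell with the particle in set 1. Of 28 synapse genes 24 fell and 0 rose, 25 over the list alone (median −0.61, adjusted p = 7.68e-13, and 0.359 with an estimated correlation). They included the vesicular glutamate transporter Slc17a7 (−1.77 ± 0.09, from 159.7 ± 8.01 to 46.7 ± 0.862 CPM), the calcium sensor Syt1 (−0.95 ± 0.09) and Snap25 of the fusion complex (−0.96 ± 0.09). Axon and cytoskeleton genes fell in 13 of 18 cases, 14 over the list alone (median −0.52, adjusted p = 3.18e-07, and 0.359 with an estimated correlation), such as the neurofilament Nefl (−1.41 ± 0.12). Excitatory neuron markers fell in 9 of 12 cases, 10 over the list alone (median −0.49, adjusted p = 4.34e-05, and 0.359 with an estimated correlation). Inhibitory neuron markers had 5 falls and 1 rise among 12, 6 and 1 over the list alone (median −0.18, adjusted p = 0.0295, 0.455 with an estimated correlation, and 0.109 without the first control library). Activity-induced genes split, with 10 rises and 7 falls among 29, 11 and 7 over the list alone (adjusted p = 0.542), Inhba falling by 1.64 and Dusp6, a brake on ERK signalling, rising by 0.95. Histone acetyltransferases and deacetylases also split, with 5 rises and 6 falls among 27, the same over the list alone (median −0.09, adjusted p = 0.61): Hdac11 fell by 0.92 and Hdac9 by 0.58, and Kat2b and Hat1 rose by 0.72 and 0.59. Hippocampal region markers had 3 rises and 3 falls among 13 (adjusted p = 0.553), and mitochondrially encoded transcripts had 0 calls among 12 (median −0.05, adjusted p = 0.619), with the same counts over the lists alone.

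Markers of other cells rose in the same set 1 particle libraries. Proliferating cell markers rose in 15 of 15 cases, the same over the list alone (median 1.83, adjusted p = 2.86e-13, and 0.359 with an estimated correlation), with Top2a, which untangles DNA in dividing cells, at 195 ± 28.7 against 46.5 ± 2.28 CPM (2.07 ± 0.11). Microglia markers rose in 12 of 13 cases, again the same (median 1.83, adjusted p = 1.05e-09, and 0.359 with an estimated correlation), with the complement gene C1qa at 60.2 ± 1.7 against 16.5 ± 2.49 CPM (1.87 ± 0.12). Choroid plexus markers rose in 5 of 6 cases (median 1.20, adjusted p = 0.00627, and 0.359 with an estimated correlation), such as Otx2 (1.78 ± 0.22). Astrocyte markers had 9 rises and 1 fall among 14, 11 and 1 over the list alone (median 0.36, adjusted p = 0.00325, and 0.402 with an estimated correlation). Gfap stood at 1101 ± 58.2 against 568 ± 84.3 CPM (0.95 ± 0.11) and Apoe at 2352 ± 51.5 against 1382 ± 322 CPM (0.77 ± 0.14, adjusted p = 0.00131). Vascular and fibroblast markers had 5 rises and 1 fall among 11, 6 and 2 over the list alone (adjusted p = 0.0785), the smooth muscle actin Acta2 rising by 2.58 and the proteoglycan Dcn having a log2 fold change of −3.36 ± 0.21. Oligodendrocyte lineage markers had 5 rises and 4 falls among 11, with a median of 0.37 and a mean of −0.11 (adjusted p = 0.61). Sox10 had 1 count with the particle and 23 in the controls, a ratio of 24.3 with a counting interval from 3.94 to 1000.1. Only Alas2 of the erythrocyte markers was measured (1 gene), and it was not called over all genes in any of the 7 comparisons.

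Immune and stress genes moved as well in set 1. Interferon-stimulated genes had 12 rises and 1 fall among 18, 15 and 1 over the list alone (median 1.22, adjusted p = 9.16e-05, and 0.443 with an estimated correlation), among them Gbp2 (1.76 ± 0.21), Ifit3 (1.78 ± 0.25) and Oasl2 (1.75 ± 0.26, 5.73 ± 0.717 against 1.71 ± 0.24 CPM). Inflammation genes rose in 9 of 12 cases, the same over the list alone (median 0.88, adjusted p = 9.16e-05, and 0.359 with an estimated correlation), such as the chemokine Cxcl10 (2.13 ± 0.25) and the adhesion molecule Icam1 (1.92 ± 0.24). Heat shock and oxidative stress genes rose in 8 of 15 cases, with 8 rises and 1 fall over the list alone (median 0.51, adjusted p = 0.00811, and 0.359 with an estimated correlation), led by the heme oxygenase Hmox1 (1.44 ± 0.11). The integrated stress response, targets of the transcription factor ATF4, had 9 falls and 3 rises among 20, the same over the list alone (median −0.22, adjusted p = 0.0211, and 0.359 with an estimated correlation), with Atf4 itself at −1.27 ± 0.09 and the glutathione-degrading Chac1 at −1.90 ± 0.19. Glycolysis and hypoxia genes had 9 falls and 3 rises among 20, 10 and 4 over the list alone (median −0.19, adjusted p = 0.0269, and 0.359 with an estimated correlation), Vegfa falling by 0.91. Endoplasmic reticulum stress genes had 8 rises and 2 falls among 15 (median 0.38, adjusted p = 0.0123, 0.424 with an estimated correlation, and 0.0798 without the second particle library). Lysosome genes had 10 rises and 3 falls among 20, 10 and 4 over the list alone (median 0.25, adjusted p = 0.0374, 0.712 with an estimated correlation, and 0.0612 without the second control library). The cathepsin Ctsd rose by 1.18.

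In set 1 as a whole, 3119 genes rose and 2874 fell of 16475 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg). The largest rises were Wisp2 (3.12), Adamtsl3 (2.79), C5ar1 (2.79), Rln1 (2.77), Ltbp2 (2.71) and Cdh26 (2.70), and the largest falls Vip (−4.23), Slc30a3 (−4.12), Nxph2 (−3.76), Dcn (−3.36), Vsig2 (−3.03) and Mvd (−2.73). C5ar1 encodes a complement receptor, Vip a peptide of inhibitory neurons and Slc30a3 the zinc transporter of synaptic vesicles. Scaling by library totals only moved the share of calls that rose from 52.0% to 65.6%. Without the second particle library 3521 genes were called in place of 5993.

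In set 2 the ApoE particle again lowered cholesterol synthesis genes. Of 20 measured, 14 fell and 0 rose, 17 over the list alone (median −0.68, adjusted p = 3.7e-16, and 0.128 with an estimated correlation). Mvd fell from 67.5 ± 2.23 to 27.7 ± 0.158 CPM (−1.29 ± 0.08, adjusted p = 6.85e-12), Idi1, which isomerizes isopentenyl diphosphate, by 0.97, Msmo1 by 0.79 and Cyp51, which demethylates lanosterol, by 0.72. Stard4 fell by 0.82 and Srebf2 by 0.54, in a sterol sensing and uptake list with 3 falls among 12 genes (median −0.10, adjusted p = 0.08). Abca1 fell from 331 ± 3.06 to 142 ± 15 CPM (−1.22 ± 0.06, adjusted p = 3.79e-12) and Srebf1, the fatty acid counterpart of Srebf2, by 0.79, among 8 falls and 0 rises in 12 LXR and efflux genes, 9 over the list alone (median −0.31, adjusted p = 3.41e-05, and 0.128 with an estimated correlation). Fatty acid genes fell in 7 of 16 cases, the same over the list alone (median −0.12, adjusted p = 6.1e-05, and 0.13 with an estimated correlation), with the desaturase Scd1 at −0.81 ± 0.06. ApoE receptor genes had 7 falls and 1 rise among 13, the same over the list alone (median −0.31, adjusted p = 0.00287, and 0.13 with an estimated correlation), Sorl1 falling by 0.71 and Vldlr rising by 0.50. Apoe was not called (−0.08 ± 0.08, adjusted p = 0.559).

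The largest changes in set 2 were in interferon-stimulated genes, which fell in 19 of 19 cases (median −5.03, adjusted p = 7.22e-32, and 0.0772 with an estimated correlation). Oasl2, an antiviral oligoadenylate synthetase-like protein, went from 377 ± 2.78 to 0.715 ± 0.0914 CPM (−9.02 ± 0.09, adjusted p = 1.14e-27). Ifit1 fell from 46 ± 2.93 to 0.171 ± 0.0739 CPM (−8.00 ± 0.21), and Stat2, which carries the interferon signal to the nucleus, fell by 2.56. Ifi44 and Isg15 fell by 6.77 and 6.68. Oas1a had 0 counts with the particle and 307 in the controls, at least 102-fold lower with 3 counts allowed over the group, and Ifi47 had 1 count against 178, a ratio of 178 with a counting interval from 31.6 to 7074. Oas1a and Oasl2 have close relatives whose reads are shared in part, so their exact levels are less certain than those of Stat2. Inflammation genes fell in 8 of 12 cases, the same over the list alone (median −1.45, unchanged with Lcn2 at its bound, adjusted p = 7.19e-07, and 0.128 with an estimated correlation). Examples were the acute-phase inhibitor Serpina3n (−2.24 ± 0.15), Socs3 (−1.74 ± 0.16) and Cxcl10 (−1.93 ± 0.22).

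Stress genes of another kind rose in set 2. The integrated stress response rose in 19 of 20 cases, the same over the list alone (median 1.497, adjusted p = 1.21e-32, and 0.128 with an estimated correlation). Atf5, a transcription factor made under this stress, rose from 18.8 ± 1.17 to 135 ± 2.65 CPM (2.85 ± 0.08, adjusted p = 3.28e-18), Chac1 from 7.55 ± 0.66 to 55 ± 10.9 CPM (2.86 ± 0.16), the mitochondrial folate enzyme Mthfd2 by 2.33 and the serine synthesis gene Psat1 by 1.39. Endoplasmic reticulum stress genes rose in 14 of 15 cases, the same over the list alone (median 0.80, adjusted p = 2.25e-21, and 0.0772 with an estimated correlation), including Herpud1 (1.64 ± 0.07) and the chaperone Hspa5 (0.84 ± 0.04). Heat shock and oxidative stress genes had 5 rises and 1 fall among 15, 7 and 1 over the list alone (median 0.20, adjusted p = 0.00429, and 0.13 with an estimated correlation). Activity-induced genes had 13 rises and 2 falls among 30, 14 and 2 over the list alone (median 0.33, adjusted p = 1.63e-05, and 0.278 with an estimated correlation), with Fosb at 2.38 ± 0.27, Npas4 at 1.02 ± 0.16 and Jun at −0.91 ± 0.06. Glycolysis and hypoxia genes had 7 falls and 1 rise among 22 measured identifiers, 10 and 1 over the list alone (median −0.11, adjusted p = 0.00306, and 0.128 with an estimated correlation).

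**Figure D2:**
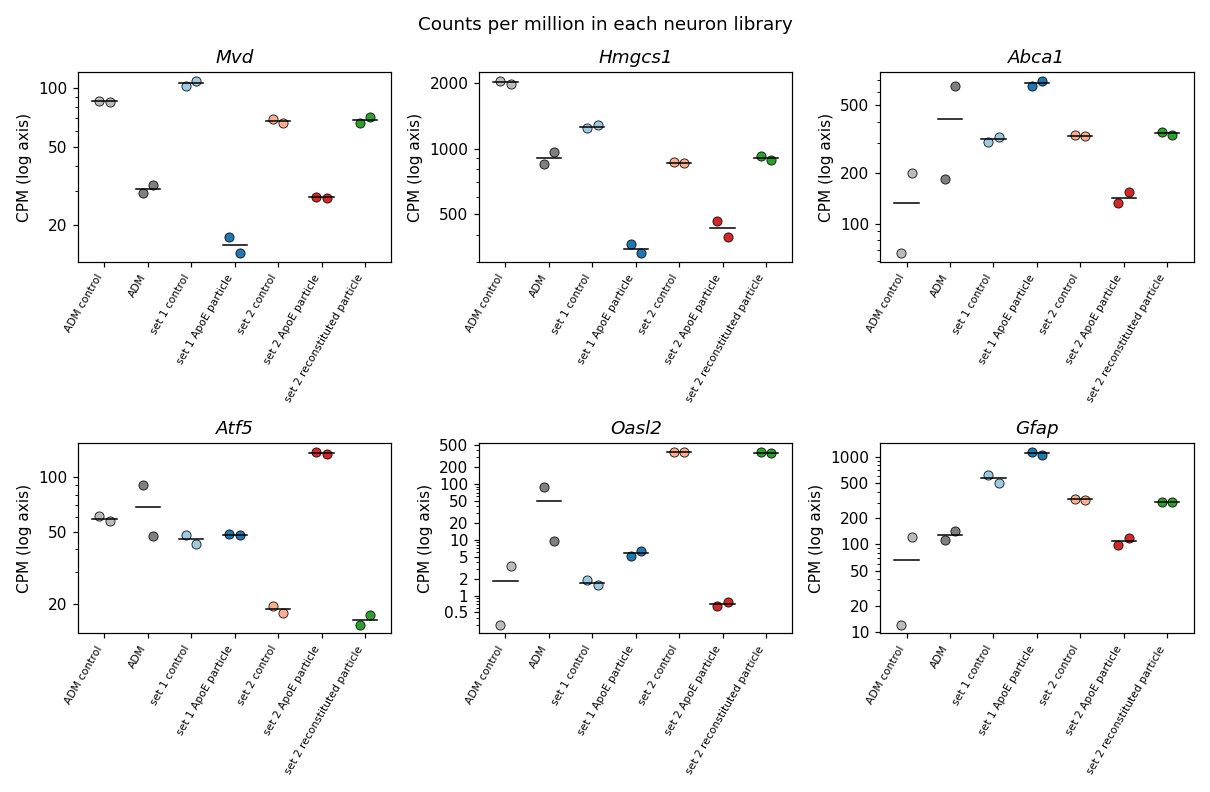
CPM (vertical axes, log scale) of Mvd, Hmgcs1, Abca1, Atf5, Oasl2 and Gfap in each library of the 7 neuron groups (horizontal axes), with points for libraries and bars for the group mean of 2 libraries. Oasl2 stands at 377 CPM in the set 2 controls and at 0.715 CPM in the set 2 ApoE particle libraries.

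Neuronal and glial transcripts also moved in set 2. Synapse genes had 14 falls and 2 rises among 28, 14 and 3 over the list alone (median −0.13, adjusted p = 0.00342, and 0.205 with an estimated correlation), with Slc17a7 at −1.09 ± 0.08 and Gria1, a glutamate receptor subunit, at −0.31 ± 0.05. Inhibitory neuron markers had 6 falls and 1 rise among 11, the same over the list alone (median −0.21, adjusted p = 0.00779, and 0.13 with an estimated correlation), the neuropeptide Npy falling by 1.01. Axon and cytoskeleton genes had 7 falls and 3 rises among 18, 9 and 3 over the list alone (median −0.09, adjusted p = 0.00512, 0.224 with an estimated correlation, and 0.058 without the second control library). Excitatory neuron markers (4 falls and 1 rise among 12, adjusted p = 0.38) were not called as a list. Astrocyte markers had 9 falls and 2 rises among 14, 9 and 3 over the list alone (median −0.28, adjusted p = 0.00047, and 0.278 with an estimated correlation). Gfap stood at 108 ± 12.9 against 326 ± 6.95 CPM (−1.59 ± 0.06), and Aqp4, the water channel of astrocytes, fell by 1.03. Proliferating cell markers had 9 falls and 1 rise among 15, 10 and 2 over the list alone (median −0.62, adjusted p = 0.00175, and 0.415 with an estimated correlation). Vascular and fibroblast markers fell in 5 of 11 cases (median −0.75, adjusted p = 0.00167, and 0.128 with an estimated correlation), with Col1a1 at −1.10 ± 0.17. Mitochondrially encoded transcripts rose in 5 of 12 cases (median 0.22, adjusted p = 0.00255, 0.415 with an estimated correlation, and 0.0882 without the second particle library). Lists of histone acetyltransferases and deacetylases (2 rises and 5 falls among 27, 2 and 6 over the list alone, adjusted p = 0.557), lysosome genes (2 rises and 1 fall among 20, median −0.01, mean 0.02), oligodendrocyte lineage (2 falls among 9, median 0.06, mean −0.04), choroid plexus (0 calls among 6) and hippocampal region markers (2 rises and 3 falls among 12, median 0.05, mean −0.01) were not called, the last 4 with an adjusted p of 0.82. Hdac2 rose by 0.26 and Hdac1 had a log2 fold change of −0.38 ± 0.08. Microglia markers were below the expression filter (0 measured).

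Over all 16388 genes tested in set 2, 1641 rose and 1976 fell with the ApoE particle (edgeR's quasi-likelihood test, Benjamini-Hochberg), and 2297 genes were called in place of 3617 without the first control library. Beside the genes above, the largest rises were Cox6a2 (3.67), a muscle-type subunit of cytochrome oxidase, the stress-induced pseudokinase Trib3 (3.08), the cationic amino acid transporter Slc7a3 (2.70) and Avil (2.54). The ribosomal RNA-like share of counts was 1.55% and 0.525% in the 2 particle libraries and 0.416% and 0.612% in the controls.

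The test of a difference between the sets asks whether the same label, ApoE particle, came with the same response. It called 5320 of 17098 genes, 2523 with a higher and 2797 with a lower fold change in set 2 than in set 1, and 3492 without the second set 1 particle library. Interferon genes had the largest median difference of the lists called (19 of 19 lower in set 2, median −6.30, adjusted p = 3.99e-21, and 0.2 with an estimated correlation), with Oasl2 at −10.80 ± 0.23. Lower in set 2 were also inflammation genes (9 of 12, 10 over the list alone, median −2.56, adjusted p = 4.72e-08, and 0.204 with an estimated correlation) and proliferating cell markers (15 of 15, median −2.48, adjusted p = 9.03e-14, and 0.204 with an estimated correlation). Lower as well were vascular and fibroblast markers (6 lower and 1 higher of 12, median −1.55, adjusted p = 0.00923) and choroid plexus markers (3 of 7, median −1.45, adjusted p = 0.0405). Astrocyte markers had 9 genes lower and 2 higher of 14 (median −0.73, adjusted p = 0.000184), and for these last 3 lists an estimated correlation gave 0.258. The choroid plexus call ended without any of 7 of the 8 libraries (adjusted p from 0.0601 to 0.317). The integrated stress response was higher in set 2 in 18 of 20 cases (median 1.63, adjusted p = 1.09e-18, and 0.2 with an estimated correlation), with Atf4 at 2.52 ± 0.11 and the asparagine synthetase Asns at 2.66 ± 0.12. Cholesterol synthesis genes fell less in set 2: 17 of 20 differed, 18 over the list alone (median 0.85, adjusted p = 3.45e-12, and 0.204 with an estimated correlation), such as Acat2 (1.66 ± 0.11) and Mvd (1.42 ± 0.13). Abca1 differed by −2.35 ± 0.11 (adjusted p = 2.81e-09) and Apoe by −0.87 ± 0.20 (adjusted p = 0.00966). Synapse genes fell less in set 2 (18 of 28, 21 over the list alone, median 0.47, adjusted p = 2.39e-09, and 0.204 with an estimated correlation). Of the 26 lists tested 16 were called for a difference, 7 upward and 9 downward, and 0 with an estimated correlation. The 16 include microglia markers, of which 0 passed the expression filter in set 2 alone, so the set 2 side of their median difference of −3.81 (adjusted p = 0.00664, and 0.258 with an estimated correlation) rests on counts near 0.

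Among 15648 genes tested in both sets, 509 fell in both (349 expected from the numbers of calls), 176 rose in both (294 expected), 605 rose in set 1 and fell in set 2 (350.4 expected), and 422 fell in set 1 and rose in set 2 (293 expected). Each of these 1027 genes with opposite calls was also called in the test of the difference. Mvd, Hmgcs1 and Slc17a7 were among the genes that fell in both, and Abca1, Gfap and Oasl2 among those that rose in set 1 and fell in set 2. Across genes, which are not independent replicates, the fold changes had a Pearson r of −0.199 and a Spearman rho of −0.12.

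**Figure D3:**
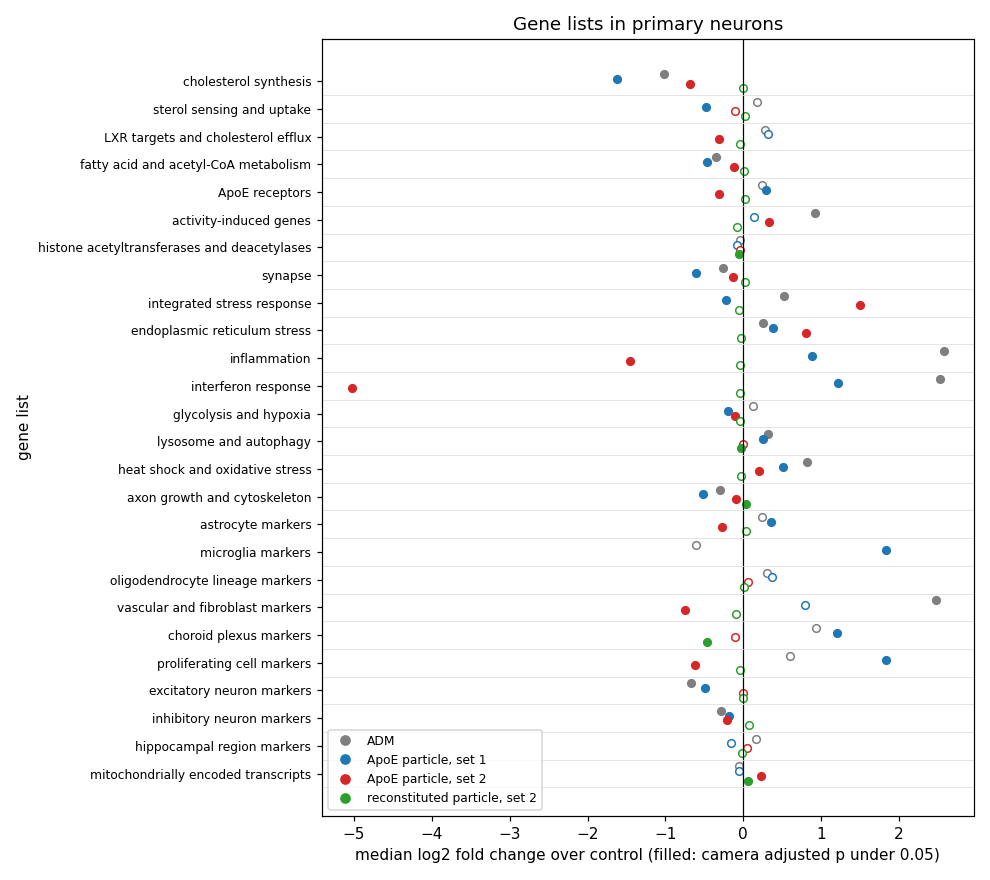
Median log2 fold change over control (horizontal axis) of each gene list (vertical axis) in the 4 neuron comparisons, with filled points for lists with a camera adjusted p under 0.05 and open points for the others. The cholesterol synthesis list lies at −1.63 in set 1, −0.68 in set 2 and −1.02 with ADM, and the interferon list at 1.22, −5.03 and 2.52.

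The reconstituted particle comparison in set 2 asks whether a particle rebuilt with ApoE acts as the ApoE particle does. No gene passed the threshold against control: edgeR's quasi-likelihood test called 0 of 16388 genes, with 776 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0775 for Pitpnm1 (0.65 ± 0.11), and DESeq2 called 0. Cholesterol synthesis genes had 0 calls among 20 and a median log2 fold change of −0.01 (adjusted p = 0.937), where Idi1 had 0.26 ± 0.09 (adjusted p = 0.986). Interferon genes had 0 calls among 19 (median −0.04, adjusted p = 0.0505), with Stat2 at −0.18 ± 0.06. Abca1 had a log2 fold change of 0.05 ± 0.06, Gfap of −0.10 ± 0.06 and Apoe of −0.10 ± 0.08. On simulated data of this design 80.3% of genes with a change of 1 log2 unit were called, but 49.2% with a change of 0.5. Of the 3617 genes called with the ApoE particle in set 2, 505 had an absolute log2 fold change of at least 1. Smaller changes with the reconstituted particle could therefore have been missed.

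Camera called 5 of 25 lists for the reconstituted particle, each with 0 called members, also over the list alone. Axon and cytoskeleton genes had a median of 0.03 (adjusted p = 0.00884, and 0.513 with an estimated correlation). Mitochondrially encoded transcripts had 0.06 (adjusted p = 0.00884, and 0.797 with it) and choroid plexus markers −0.46 (adjusted p = 0.00884, and 0.757 with it). Histone acetyltransferases and deacetylases had −0.05 (adjusted p = 0.0365, and 0.513 with it) and lysosome genes −0.03 (adjusted p = 0.0406, and 0.513 with it). Ttr, the thyroxine carrier made by choroid plexus, had 22 ± 2.82 against 45 ± 18 CPM (−1.03 ± 0.41, adjusted p = 1). Each call also ended with a library left out. That held for the histone enzyme and lysosome lists without any 1 of the 4 control and reconstituted libraries (adjusted p up to 0.0978 and 0.254), for mitochondrial transcripts without the second control or the first reconstituted library (0.431 and 0.918), for choroid plexus markers without the first control or the second reconstituted library (0.254 and 0.208) and for the axon list without the first control library (0.295).

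Compared directly, the 2 particles of set 2 differed in 3319 of 16388 genes, with 1864 higher and 1455 lower with the reconstituted particle. Interferon genes were higher in 19 of 19 cases (median 5.04, adjusted p = 1.59e-32, and 0.073 with an estimated correlation), Oasl2 by 8.97 ± 0.09, Irf7 by 6.41 ± 0.21 and Oas1a, with 275 counts against 0, at least 96.9-fold. Cholesterol synthesis genes were higher in 15 of 20 cases, 17 over the list alone (median 0.70, adjusted p = 3.76e-16, and 0.118 with an estimated correlation), with Mvd at 1.31 ± 0.08 (adjusted p = 4.44e-12), and Abca1 was higher by 1.26 ± 0.06. The integrated stress response was lower in 19 of 20 cases (median −1.58, adjusted p = 3.56e-34, and 0.118 with an estimated correlation), with Atf5 at −3.04 ± 0.08, Chac1 at −3.28 ± 0.17 and Cox6a2 at −4.10 ± 0.37. The endoplasmic reticulum stress list was lower in 14 of 15 cases (median −0.80, adjusted p = 1.75e-22, and 0.073 with an estimated correlation). Astrocyte markers had 9 genes higher and 1 lower of 14 (median 0.32, adjusted p = 2.9e-05, and 0.219 with an estimated correlation), Gfap by 1.49 ± 0.06. In all, 18 of 25 lists differed, 14 upward and 4 downward, and 0 with an estimated correlation (smallest adjusted p = 0.073).

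The ApoE particle and reconstituted particle fold changes share control libraries, which alone ties them together. Their Pearson r across 16388 genes was 0.256, Spearman rho 0.277 and covariance 0.044. In 40 simulated data sets with unchanged groups against the same controls, r averaged 0.496 (0.471 to 0.516) and covariance 0.0318 (0.0289 to 0.0340). The observed covariance thus lay above the simulated range and the observed r below it. Because r is divided by the spread of the fold changes, real changes with 1 particle lower it. The lower r therefore does not show that the particles were less alike than unchanged groups. With 2 control libraries the controls were not split.

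The ADM comparison concerns neurons treated with ADM, which the labels do not spell out. No gene passed the threshold: edgeR's quasi-likelihood test called 0 of 16191 genes, with 1426 at an unadjusted p under 0.05 and a smallest adjusted p of 0.215 for Timp1 (4.95 ± 0.27), an inhibitor of matrix proteases, while DESeq2 called 333, 277 upward and 56 downward. On simulated ADM data 56 of 132 DESeq2 calls were genes without a planted change, so these 333 calls are uncertain. Cholesterol synthesis genes fell as a list: 0 of 20 passed over all genes and 18 over the list alone, all downward (median −1.02, adjusted p = 3.07e-24, and 0.285 with an estimated correlation). Mvd had 30.6 ± 1.86 against 85.1 ± 0.437 CPM (−1.48 ± 0.14, adjusted p = 0.396) and Hmgcs1 906 ± 82.2 against 2026 ± 48.9 CPM (−1.16 ± 0.13, adjusted p = 0.396). Fatty acid genes fell as a list with 3 of 16 members called over the list alone (median −0.34, adjusted p = 2.14e-05, and 0.285 with an estimated correlation). The sterol sensing list, with 4 of 11 lower over the list alone, had a median of 0.18 and a mean of −0.29 and was not called (adjusted p = 0.06). Abca1 had 414 ± 328 against 132 ± 92.9 CPM (1.64 ± 0.79, adjusted p = 0.607), and Apoe 336 ± 168 against 396 ± 332 CPM (−0.24 ± 0.72, adjusted p = 0.946).

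Several lists rose with ADM, each with 0 members called over all genes. Inflammation genes had 10 of 16 called over the list alone, all upward (median 2.57, adjusted p = 4.5e-09, and 0.43 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, had 2.37 ± 0.23 (adjusted p = 0.396), and Ccl7 had 114 counts against 3. Interferon genes had 18 of 18 fold changes above 0 and 0 calls over the list alone (median 2.52, adjusted p = 5.11e-09, and 0.489 with an estimated correlation), with Bst2 at 3.71 ± 0.91 (adjusted p = 0.532). Activity-induced genes had 11 called upward and 1 downward of 29 over the list alone (median 0.93, adjusted p = 3.9e-06, and 0.285 with an estimated correlation), such as Junb at 2.42 ± 0.28 and Egr2 at 2.83 ± 0.41. Heat shock and oxidative stress genes had 8 of 15 called over the list alone (median 0.81, adjusted p = 1.33e-05, and 0.43 with an estimated correlation), with Hmox1 at 205 ± 129 against 19.2 ± 6.72 CPM (3.41 ± 0.57, adjusted p = 0.428). Vascular and fibroblast markers had 5 of 11 called over the list alone (median 2.47, adjusted p = 3.55e-05, and 0.43 with an estimated correlation), with Flt1 at 2.83 ± 0.47 (adjusted p = 0.428). The integrated stress response, with 1 of 20 called over the list alone (median 0.52, adjusted p = 0.000437, and 0.703 with an estimated correlation), the endoplasmic reticulum stress list (median 0.26, adjusted p = 0.00142, and 0.6 with an estimated correlation) and the lysosome list (median 0.32, adjusted p = 0.00812, and 0.71 with an estimated correlation) also rose. The direction of the integrated stress list turned without the first ADM library.

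Neuronal lists fell with ADM, again with 0 members called, also over the list alone. The synapse list had 25 of 28 fold changes below 0 (median −0.27, adjusted p = 3.9e-06, and 0.43 with an estimated correlation), with the scaffold Shank1 at −0.63 ± 0.12 (adjusted p = 0.473). The axon list (median −0.30, adjusted p = 2.3e-05, and 0.285 with an estimated correlation), the excitatory neuron markers (median −0.67, adjusted p = 8.12e-05, and 0.43 with an estimated correlation) and the inhibitory neuron markers (median −0.29, adjusted p = 0.00812, and 0.556 with an estimated correlation) fell too. With an estimated correlation 0 of 26 ADM lists were called. The other 12 lists tested were not called, among them the astrocyte (median 0.23, mean −0.07, adjusted p = 0.803), microglia (median −0.61, adjusted p = 0.354) and histone enzyme lists (median −0.04, adjusted p = 0.446).

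The ADM libraries of a group stood far apart, with a common dispersion of 0.0823 against 0.00672 in set 1 and 0.00374 in set 2. Part of this spread was shared by replicate number. The difference between library 1 and library 2 correlated at 0.596 between the control and ADM groups across 11691 genes. The unpaired test counts that shared part as spread, and the labels do not say what equally numbered libraries have in common. Oasl2 had 90.3 and 9.64 CPM in the ADM libraries, Lcn2 281 and 3.8 CPM, Col1a1 18 and 246 CPM, and Gfap 12.2 and 121 CPM in the controls (genes chosen after their values were seen). The ribosomal RNA-like share was 2.84% and 1.33% with ADM and 0.635% and 0.113% in the controls. Without the first ADM library 641 genes were called, without the second 47, and without either control library 0. The integrated stress call also ended without the first ADM library (adjusted p = 0.785), the endoplasmic reticulum stress call without the second control or the second ADM library (0.128 and 0.0545), the lysosome call without the first control or second ADM library (0.193 and 0.434) and the inhibitory marker call without the second ADM library (0.505).

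Fold changes with ADM and with the set 1 particle had a Pearson r of 0.515 and a Spearman rho of 0.463 across 15320 genes, and 66.9% of genes had the same sign. ADM against set 2 gave an r of −0.324 and a rho of −0.0872 across 15329 genes. In the test of the difference between ADM and the set 1 particle edgeR called 0 of 17292 genes, with 1768 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0531 for Dcn (3.73 ± 0.30), and no other tool was run on it. Without the first or second ADM library 377 and 555 genes were called. Cholesterol synthesis genes were less lowered by ADM as a list (median difference 0.51, 7 of 20 over the list alone, adjusted p = 5.07e-09, and 0.318 with an estimated correlation), with Mvd at 1.21 ± 0.17 and Dhcr7 at 0.98 ± 0.14 (adjusted p = 0.107 each). Activity-induced genes differed upward (median 0.81, 3 of 30 over the list alone, adjusted p = 1.78e-05, and 0.318 with an estimated correlation), with Junb at 2.38 ± 0.32 (adjusted p = 0.105). Microglia (median −2.25, adjusted p = 5.22e-06) and proliferating cell markers (median −1.15, adjusted p = 2.24e-07) differed downward, both with an adjusted p of 0.573 with an estimated correlation. In all 11 of 26 lists differed, 9 upward and 2 downward, and 0 with an estimated correlation (smallest adjusted p = 0.318) or with fry. Treatment and experiment cannot be told apart here, since each treatment was measured only in its own experiment.

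The hippocampus libraries address what FC does to the tissue of mice given a control shRNA, and what an shRNA against Apoe does with FC. There is 1 library per group, so each ratio compares those libraries, not the conditions. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188 in mm10) stood at 1697 CPM in control shRNA without FC, 2797 CPM in control shRNA with FC and 1384 CPM in ApoE shRNA with FC. The log2 ratio was 0.72 (exact 95% counting interval 0.70 to 0.74) for FC and −1.02 (−1.04 to −0.99) for ApoE shRNA against control shRNA, both with FC. The last ratio is taken against the library with the highest Apoe. Against control shRNA without FC the ApoE shRNA library was lower by less, at 1384 against 1697 CPM. The ratio of −1.02 is therefore not a measure of the knockdown alone.

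The control shRNA library with FC held far more immune transcripts than the one without. All 19 interferon genes were at least 2-fold higher (median log2 ratio 4.36), with Gbp2, an interferon-induced GTPase, at 303 against 3.03 CPM (6.63, 6.26 to 7.06) and Oasl2 at 170 against 3.58 CPM (5.56, 5.21 to 5.95). Inflammation genes were at least 2-fold higher in 10 of 12 cases (median 2.43), with the complement protein C3 at 182 against 2.64 CPM (6.09) and Ccl5 at 31.8 against 0.275 CPM (6.71). Microglia markers were at least 2-fold higher in 11 and lower in 1 of 15 cases (median 1.95), with Ctss at 669 against 65.3 CPM and C1qa at 453 against 46.7 CPM. Lists of endoplasmic reticulum stress (median 0.64), lysosome (0.46), oligodendrocyte lineage (0.40) and activity-induced genes (0.36) were also higher than any of the 10000 random lists, as the immune lists were (percentile 100 each), with the lysosomal protease Ctsd at 346 against 103 CPM and Inhba at 33.4 against 7.27 CPM. Gfap had 2117 against 570 CPM (1.89), while the astrocyte list had a median of 0.09 and a mean of 0.32 (percentile 93.2).

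Cholesterol synthesis genes were lower in that FC library in 17 of 19 cases, 14 of them with an interval below 0, and the median of −0.25 lay at percentile 0 of the random lists. The squalene epoxidase Sqle had 41.4 against 66.4 CPM (−0.68, −0.82 to −0.55). Fatty acid genes (median −0.20, percentile 0.47), synapse (−0.22, 1.53), axon (−0.20, 1.53) and inhibitory neuron lists (−0.23, 1.2) were lower, with Gria1 at 554 against 1014 CPM. Abca1 had 113 against 54.2 CPM (1.06) and Apod 341 against 107 CPM (1.68), in an LXR list with a median of 0.26 (percentile 98.6). Excitatory neuron (0.42, percentile 99.99), integrated stress (0.33, 99.9) and heat shock lists (0.25, 98.8) were higher. The remaining lists had percentiles from 7.28 to 93.8. Those were sterol sensing (median −0.12, mean 0.09), glycolysis and hypoxia (−0.13, mean 0.14), proliferating cells (4 measured), histone enzymes (0.06), ApoE receptors (0.10), vascular markers (0.22), hippocampal region markers (0.07) and mitochondrial transcripts (0.05). Among region markers Fibcd1, a marker of the CA1 field, had 35.9 against 176 CPM (−2.29).

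Of 12510 genes with at least 100 counts, 832 were at least 1 log2 unit higher and 147 lower with FC. The largest rises were the class II antigen H2-Aa (0.826 to 445 CPM), the chemokine Cxcl9 (1 count against 723, a ratio of 738 with an interval from 132 to 29205), Gbp10 (3 counts against 1299, a ratio of 442, 151 to 2147), Gbp8, Igkv6-32 (0 against 176 counts, at least 59.9-fold) and Cd8b1, a co-receptor of cytotoxic T cells (0 against 144 counts, at least 49.0-fold). The largest falls were Dlk1 (17.8 to 2.53 CPM), Vgll3, Slc9a4, Dio3, Gpr101 and Trpc7. Members of the Gbp family and immunoglobulin segments share reads, so their single values are uncertain.

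In the ApoE shRNA library with FC these lists ran the other way against control shRNA with FC. The control shRNA library with FC enters both ratios on opposite sides, so part of this turn is built in. How large that part is was not computed. All 19 interferon genes were at least 2-fold lower (median −4.14), as were 9 of 12 inflammation genes (median −2.41) and 13 of 15 microglia markers (median −2.22), all at percentile 0. Gbp2 had 2.22 CPM, C1qa 36.6 CPM, C3 0.794 CPM and Gfap 457 CPM. Endoplasmic reticulum stress (−0.59) and lysosome lists (−0.38) also lay at percentile 0, and astrocyte (−0.40), oligodendrocyte (−0.44) and vascular lists (−0.57) at 0.05, 0.05 and 0.515. Cholesterol synthesis genes had a median of 0.17 (percentile 98.4) with 8 intervals above 0 and 3 below, Sqle at 61.1 CPM (0.56) and Idi1 at −0.69 (−0.98 to −0.40). Synapse (0.38, percentile 99.5) and axon lists (0.33, 98.9) were higher, with Gria1 at 1110.5 CPM. Abca1 had 47.7 CPM (−1.25) and Npc2, a lysosomal sterol carrier, 53.5 CPM (−1.75).

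Mitochondrially encoded transcripts were lower in the ApoE shRNA library in 10 of 10 cases (median −1.15, percentile 0). mt-Nd1 had 627 against 3765 CPM and mt-Nd6 10.001 against 398 CPM, and the mitochondrial share of counts was 1.84% against 4.12%, and 4.24% in control shRNA without FC. Excitatory neuron (−0.31, percentile 1.23), activity-induced (−0.16, 3.17), LXR (−0.27, 4.31) and region lists (−0.25, 5.52) were low among random lists. Fatty acid (0.19, 92.1), inhibitory neuron (0.22, 94.3), sterol sensing (median 0.14, mean −0.08, 85.5) and glycolysis lists (0.20, 75.9) were above the middle, and integrated stress, heat shock, histone enzyme, ApoE receptor and proliferating cell lists lay from 12.7 to 53.1. Choroid plexus markers had 2 measured members, with Ttr at 1.05, 33.8 and 2.43 CPM and Kl at 21.4, 15.1 and 23.3 CPM in control shRNA without FC, with FC and ApoE shRNA. The 2 measured erythrocyte genes, Hba-a1 and Hbb-bs, had 29.7 and 33.6, 17.4 and 21.9, and 9.74 and 11.6 CPM in the same order.

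Of 12474 genes, 101 were at least 1 log2 unit higher and 1182 lower in the ApoE shRNA library. The largest rises were Col6a4, Capn11, Dlk1 (2.53 to 19 CPM), Vgll3, Gpr101 and Fibcd1 (35.9 to 181 CPM). The largest falls were Ighg2b (1777 counts against 0, at least 629-fold), Igha (at least 594-fold), Cst7, a cystatin of activated microglia (845 counts against 0, at least 299-fold), Igkc (3722 counts against 2, a ratio of 1977 with an interval from 547 to 16332), Igkv3-2 and Ighv1-9 (at least 260-fold and 224-fold). Apart from Cst7 these are immunoglobulin genes.

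**Figure D4:**
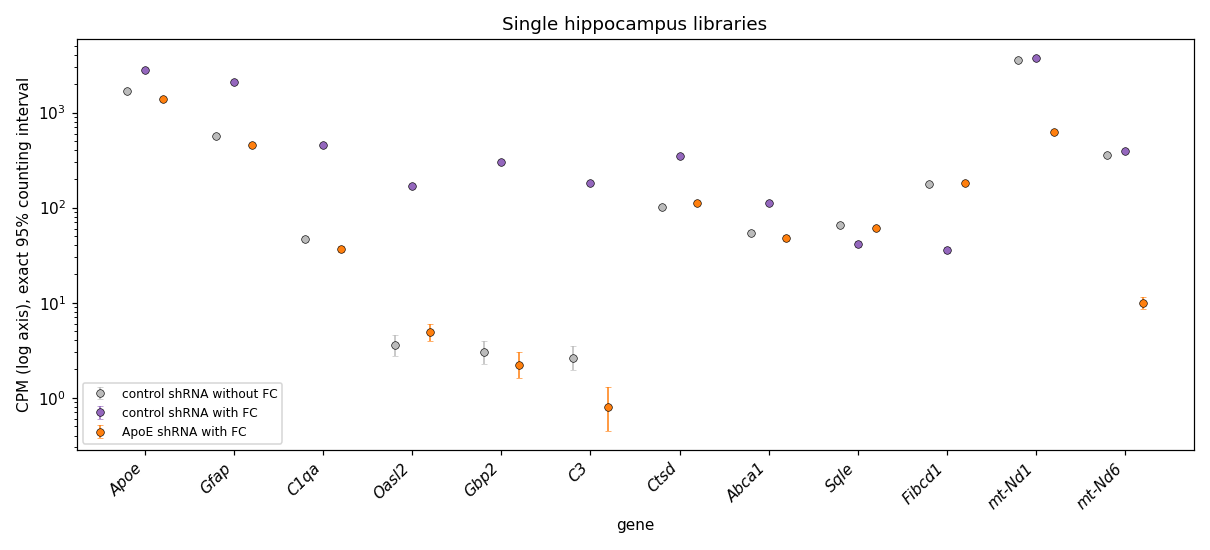
CPM (vertical axis, log scale) of 12 genes (horizontal axis) in the 3 single hippocampus libraries, with points for libraries and bars for the exact 95% counting interval. Gbp2 stands at 3.03 CPM without FC, 303 CPM with FC in control shRNA and 2.22 CPM in ApoE shRNA with FC.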

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

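All 3 tests of explanations in this part were chosen after the results were seen, and the test of the difference between the sets was chosen before the data were examined. No group held 4 or more libraries, so none was examined for a sample far from the others.

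The response to the ApoE particle differed between set 2 and set 1, by the interaction test, in 5320 genes. Of these, 605 were called upward in set 1 and downward in set 2, among them Abca1, Gfap and Oasl2, and 422 were called downward in set 1 and upward in set 2, among them Chac1 and Asns. As lists, with the difference (set 2 minus set 1) called by camera and opposite calls in the 2 sets, the median differences in log2 fold change were −6.30 for interferon-stimulated genes, −2.56 for inflammation, −2.48 for proliferating cell markers, −0.73 for astrocyte markers, −0.39 for ApoE receptors and 1.63 for the integrated stress response. With an estimated correlation none of these 6 list differences was called (adjusted p from 0.2 to 0.258).

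Some counts lay in values that no comparison used. In set 2, 1489 genes held counts for the reconstituted particle libraries but none for the control and ApoE particle libraries, and 12 of them had at least 10 counts in both reconstituted libraries. Symbols stored as dates, such as those of septins, were found for 12 of the 1489 genes, and whether these are the same 12 was not checked. Together the 1489 genes held 0.232% and 0.226% of the counts of the 2 libraries.

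Interferon-stimulated genes fell with the particle in set 2 and rose in set 1 (adjusted p of the lists 0.0772 and 0.443 with an estimated correlation). A smaller share of astrocytes in the set 2 particle cultures is argued against for 18 of the 19 genes, whose upper 95% limit lay under the lower limit of the lowest astrocyte marker, Gfap (−1.59), and stays open for Ifit2 (−1.37, named after its values were seen). A set 2 table joined from 2 counting runs is argued against by the reconstituted particle libraries, which carry values the other libraries lack and yet had an interferon median of −0.041 against the same controls. A candidate explanation is that the set 2 control cultures were in another interferon state than those of set 1, since the list had a median log2 ratio of 4.12 between the 2 control groups (18 of 18 genes higher in set 2) and −1.86 between the 2 ApoE particle groups. That state, the set and a biological effect of the particle cannot be told apart, because each set has its own controls and libraries, and a particle that ends an interferon state already present remains open. The astrocyte test covers set 2 only. In set 1 microglia markers rose in 12 of 13 cases by a median of 1.83, more than the interferon median of 1.22. A larger share of microglia was not tested and stays open for the set 1 rise.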

How the results depend on the processing

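The alternatives were chosen before the data were examined, apart from the crossed replicate block. Named genes of the neuron comparisons kept direction and side of the threshold in 6688 of their tests under alternatives, became called in 163, lost the call in 119 and moved in 20. Lists kept both in 1301 tests, lost the call in 179, gained it in 63, moved in 63 and turned in 5. No gene called in the report was called in the other direction under an alternative (0).

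With an estimated correlation 0 lists were called in each of the 7 comparisons. On simulated data it also missed the planted list for ADM, set 1 and ADM against set 1. The fry test called 0 for ADM, for the reconstituted particle against control and for ADM against set 1. It called 15 lists in set 1 and 16 with the ApoE particle in set 2. Between the particles of set 2 fry called 17, and for the difference between the sets 20. Of the camera calls it kept 15 of 19, 15 of 18, 16 of 18 and 16 of 16 in that order. Requiring an absolute log2 fold change of 1 left 1881 genes in set 1 (1462 upward and 419 downward), 505 in set 2 (147 and 358) and 479 between the particles of set 2 (331 and 148), so the near-even splits over all calls did not hold among the larger changes. In set 1, DESeq2 called 4765 genes, and in set 2, 2499.

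For ADM the count of 0 became 333 with DESeq2, 128 without a filter on low counts and 465 with the replicate block, and ran from 0 to 641 with 1 library left out. For the reconstituted particle against control it became 8 without a filter, 1 with the replicate block, 4 with the crossed block and 4 in a fit of those 2 groups, and ran from 1 to 4 with 1 library left out, where 2 to 8 lists were called. For the difference between ADM and set 1 the count of 0 became 1 with median-of-ratios scaling, 62 without a filter and 502 with the replicate block, and ran from 0 to 555. With 1 library left out the counts ran from 3521 to 7610 in set 1, from 2297 to 3836 in set 2, from 2249 to 3314 between the particles of set 2 and from 3492 to 6245 for the difference between the sets. These fits hold 1 library in a group and assume that it varies like the others. Why the counts moved was not tested beyond this loss of libraries and the correlation by replicate number given next.

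The replicate block pairs libraries by number. The correlation between residuals of equally numbered libraries was 0.596 for ADM, 0.0512 in set 1, and −0.151, −0.135 and 0.0973 for the 3 pairs of groups in set 2. With it 6386 genes were called in set 1 and 3248 in set 2. The crossed block, added after the data had been seen, called 4234 genes in set 2.

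In the ADM comparison 4 lists turned with 1 library left out: astrocyte markers without the first control (adjusted p = 0.00122, range over the libraries left out 0.000465 to 0.232), microglia markers without the second control (0.0485, range 2.14e-07 to 0.456), the integrated stress response without the first ADM library (0.785, range 3.38e-22 to 0.785) and proliferating cell markers without the second (0.0298, range 7.2e-07 to 0.504). Proliferating cell markers also turned for the reconstituted particle without the first control (0.0379, range 0.0277 to 0.932). The cause was not tested.

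Of genes called in both sets with an absolute log2 fold change of at least 1, 34 had the same direction and 153 opposite ones. Among genes called in either comparison, fold changes had an r of 0.608 for ADM and set 1, −0.227 for the 2 sets, 0.305 for the 2 particles of set 2 and −0.50 for ADM and set 2. In the hippocampus a minimum of 10 counts gave 1852 genes higher and 737 lower with FC, and 515 higher and 2580.0 lower with ApoE shRNA. Hippocampus gene ratios stayed within their counting interval in 668 cases and moved in 28, and lists stayed in 141 and moved in 9.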

Other observations

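All 8 tests of explanations in this part were chosen after the results were seen.

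Cholesterol synthesis genes fell with the ApoE particle in set 1 and set 2 and, as a list only, with ADM (adjusted p 0.359, 0.128 and 0.285 with an estimated correlation). A changed share of astrocytes is argued against as the cause in sets 1 and 2. The list fell in set 1 (median −1.63), where astrocyte markers rose, as well as in set 2, where astrocyte markers fell (0.402 and 0.278 for the astrocyte lists with an estimated correlation). ADM was not part of this test, and its astrocyte list was not called (camera, adjusted p = 0.803). A loss of neuronal transcripts by the size of the synapse median is argued against as the whole cause in sets 1 and 2. In set 2, 14 of the 20 genes had an upper 95% limit under the synapse median of −0.13, and in set 1 19 had one under −0.61. Single neuronal genes such as Slc17a7 fell by more than the cholesterol synthesis median in both sets. A stronger loss of some neuronal transcripts therefore stays open, and ADM was not part of this test. Sterol delivered by the particle would lower Insig1, Stard4 and Srebf2 and raise the LXR targets Abca1 and Abcg1. In set 2 Abca1 instead had a log2 fold change of −1.22. Astrocyte markers had 9 falls and 2 rises in the same libraries, with Gfap lower still (−1.59). A smaller share of astrocytes could therefore also lower Abca1, and its fall does not decide on sterol supply in set 2. In set 1 Abca1 rose by 1.11, and Insig1, Stard4, Srebf2 and Abcg1 were called in the direction that supply needs. Astrocyte and microglia markers rose there as well (medians 0.36 and 1.83), so the Abca1 rise may reflect cell make-up. For set 1 alone, sterol supply may account for the fall of cholesterol synthesis genes and stays a hypothesis.

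In the hippocampus, the interferon, inflammation and microglia lists were higher in control shRNA with FC than in both other libraries. More microglia alone is argued against for 11 of the 19 interferon genes, whose lower counting limit lay above the upper limit (3.44) of the most raised microglia marker, Ctss, and for 4 of the 12 inflammation genes by the same measure, and stays open for the other 8 interferon and 8 inflammation genes and for the microglia list. A different dissection also stays open, because the 2 choroid plexus markers disagree: Ttr had a log2 ratio of 4.98, above the interferon median of 4.36, and Kl one of −0.50. An immune reaction of 1 animal or sample, the dissection and an effect of FC that ApoE shRNA prevents cannot be told apart, because the group holds 1 library. The same library held transcripts known from lymphocytes, with 144 counts of Cd8b1 against 0 without FC, and 3722 counts of Igkc against 2 in ApoE shRNA with FC.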
